A study of Mus musculus with 9 samples.

How the data were processed

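Gene expression was measured by RNA sequencing in 9 libraries of a mouse podocyte line that the labels name MCP5. Podocytes are the epithelial cells that cover the glomerular capillaries of the kidney. The labels give the genotype as wild type and place 3 libraries in each of 3 groups: untreated control, high glucose (50 mmol/L) and advanced glycation end products (AGEs, 400 µg/mL). AGEs are proteins modified by reducing sugars. The duration of treatment, the glucose level of the control medium, an osmotic control and a control for the carrier protein of the AGEs are not given in the sources used here or not analysed here. Per the labels' protocols, total RNA was extracted with TRIzol, and RNA fragments were reverse-transcribed with SuperScript II. The titles number the libraries 1 to 3 within each group but do not state separate cultures, so p-values measure only the spread between these libraries, which may be technical.

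The authors deposited 1 table with whole-number read counts per gene and FPKM values per gene (fragments scaled to transcript length and library size), with a column of each unit for every library, per the file headers. Per the submitters' processing notes, cutadapt 1.9, FastQC and the genome build GRCm38 were used. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Reads from overlapping genes on opposite strands and from near-identical gene copies are therefore uncertain. In the deposited FPKM columns a gene with a count of 0 was written as 0.0001. For a gene, FPKM divided by count was nearly constant across libraries after 1 factor per library, with a median SD of 0.00055 on the log2 scale over 10659 genes with more than 200 counts in each library. Low counts in the deposited table fell on 4 and 8 more often than on neighbouring numbers (9186 and 4896 entries, against 2519 at 3 and 1632 at 7), so that 1 fragment may have added more than 1 count. The floor of 3 counts used for folds against 0 counts covers counting error only and is then too low. The table held 55385 genes, of which 26477 had at least 1 count in some library. Of the gene identifiers, 55144 were found in the GENCODE mouse release 21 annotation, 51991 of them with the same start, end and strand.

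Total counts ranged from 46284878 to 77242281 per library. Replicate libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom from 47.6 to 110 (109.52 at the most, between AGEs libraries 1 and 3), so no library was counted as a copy of another. A count test was fitted with edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest) in R 4.3.3, on the counts as deposited. The filter was filterByExpr with the groups, which left 17680 genes, and the scaling was TMM, with factors from 0.935 to 1.10. All 9 libraries entered 1 fit with 3 group means and no covariate, so the groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.278. Each test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05 with no fold threshold. Levels are CPM (counts scaled to library size) with the TMM factors, as mean ± SD over 3 libraries. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. A fold against a group with 0 counts is a lower bound, against a floor of 3 counts over the group.

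The procedure was tested on simulated counts of 17008 genes with 200 genes changed per treatment. The changed genes were drawn only from genes above a minimum expected count, so the shares recovered do not cover genes with low counts. For high glucose against control it recovered 67% of genes changed 2-fold and 90% of genes changed 4-fold with 10 false calls. For AGEs against control the shares were 62% and 83%, with 6 false calls. The cutoff after adjustment depends on how many genes change, and the real comparisons called 6946 and 15 genes. The shares recovered therefore do not carry over to them.

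The groups, the tests, the gene lists, the rule for named genes and the processing alternatives were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall in each treatment against control (5 and 5 for AGEs against high glucose). They had to be called, reach a mean FPKM of 1 in a group, not overlap between the groups and carry an ordinary symbol. With 3 libraries against 3, chance leaves 10% of genes without overlap. The rule also named up to 3 called members of each list by smallest p, and always a set of genes fixed beforehand, among them Nphs1, Synpo, Wt1, Podxl, Ager, Txnip and Arrdc4. Another gene of that set is not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so.

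The 28 gene lists covered podocyte markers, extracellular matrix and TGF-beta targets, NF-kB and inflammatory mediators, interferon-stimulated genes, NRF2 targets and antioxidant enzymes, glycolysis and glucose transport, the osmotic stress response (NFAT5 targets), ER stress and the integrated stress response, cholesterol biosynthesis, fatty acid synthesis and storage, fatty acid oxidation and PPAR-alpha targets, the cell cycle, p53 targets and apoptosis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, AGE receptors and glyoxal detoxification, autophagy and lysosome, actin cytoskeleton and focal adhesion, ribosomal proteins, Notch, Wnt and Hippo targets, immediate-early genes, heat shock proteins, markers of other cell types (endothelial, mesangial and fibroblast, tubular, parietal epithelial, leukocyte) and nuclear and non-polyadenylated transcripts as a sign of RNA quality. All 662 listed members were found in the table, 6 of them under another symbol. Members that the filter on low counts removed, Wt1 among them, were not tested. List sizes in the results are of the members tested. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Counts of called members are also given adjusted over the list alone. KEGG pathways with 15 to 300 tested genes, as annotated in the deposited table, were tested with both forms of camera and not with fry. This test was added after the data were seen.

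Both treatments were compared with the same 3 control libraries. The correlation of their fold changes is therefore given beside its value in 20 simulations of unchanged groups that share the controls. The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a mean CPM of at least 1, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with an FPKM of at least 0.5 in 3 libraries, a log2 fold change of at least 1, a fit of only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. An offset for GC content and transcript length was chosen after seeing the data. Figures were drawn with matplotlib from the result tables.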

Results

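RNA sequencing was used to ask which genes differ among cultured mouse podocytes left untreated, given high glucose, or given advanced glycation end products (AGEs). The cell line, labelled MCP5, was a wild-type podocyte line, and each group had 3 libraries. Total counts were 66364072, 70705840 and 62193640 in control, 77242281, 46284878 and 71972434 in high glucose, and 68072395, 72299415 and 73427057 in AGEs. The first principal component held 41.0% of the variance and separated the high glucose libraries (85.8 to 90.2) from the control and AGEs libraries (−49.0 to −40.4). On the second component, with 11.9% of the variance, AGEs library 3 stood apart from the rest at 82.8, with AGEs libraries 1 and 2 at −46.2 and −23.1. The 10 most abundant genes took 7.22 ± 0.07% of the counts in control, 4.50 ± 0.29% in high glucose and 7.23 ± 0.32% in AGEs (mean ± SD, n = 3). Wt1, a podocyte transcription factor that the rule for named genes always includes, had 11 counts in high glucose library 2 and 0 in the others.

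To evaluate the response to high glucose, the high glucose libraries were compared with control. Genes of the endoplasmic reticulum (ER) stress and integrated stress response fell together. Of 30 members tested, 29 were lower in high glucose and 0 were higher, with a median log2 fold change of −1.78. Ddit3, which encodes the stress-induced transcription factor CHOP, went from 1672 ± 18.7 CPM (counts scaled to library size) in control to 47.3 ± 3.96 CPM in high glucose (mean ± SD, n = 3). It was 35.3-fold lower (log2 fold change −5.14, SE 0.11, adjusted p = 2.91e-08). In the opposite direction Txnip, a thioredoxin-binding arrestin whose transcription responds to glucose, rose 18.4-fold from 8.69 ± 2.25 to 159 ± 4.71 CPM (log2 fold change 4.20, SE 0.22, adjusted p = 1.92e-06). Its relative Arrdc4 rose by 1.44 on the log2 scale (adjusted p = 0.000548). By the edgeR quasi-likelihood test, 6946 of 17680 genes were called, 3466 higher and 3480 lower in high glucose. A change of at least 2-fold was seen in 2419 of them, 1482 higher and 937 lower. With limma on log2(FPKM + 1) the split was 4588 higher and 2362 lower (66.0% higher, against 49.9% by edgeR). With a pseudocount of 0.1 it was 4493 and 2362 (65.5% higher). The median log2 fold change of all genes was 0.12 and 0.15 on these scales and 0.03 by edgeR, so directions of small changes are relative to that shift. No osmotic control was analysed here.

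Within the ER stress list, Pdia4, a protein disulfide isomerase of the ER, was 4.57-fold lower (2072 ± 37.7 to 453 ± 5.33 CPM, adjusted p = 1.42e-07). Creld2, an ER protein induced by unfolded protein, was 6.33-fold lower (836 ± 48.7 to 132 ± 9.77 CPM, adjusted p = 1.42e-07). The member that did not pass was Ddit4, with a log2 fold change of −0.12 (adjusted p = 0.553). Together the list took 4.84 ± 0.09% of all counts in control and 1.38 ± 0.03% in high glucose. The list was lower by camera (adjusted p = 5.92e-21), and this call held with an estimated correlation (adjusted p = 0.000905). The same 29 members passed when adjusted over the list alone. Ddit3 (ENSMUSG00000025408, GRCm38 chromosome 10, 127290774 to 127296288, plus strand) overlaps Mars on the opposite strand, which had 141724 counts over all libraries against 676338 for Ddit3. Txnip (ENSMUSG00000038393) lies on chromosome 3 from 96557957 to 96561883, plus strand. Markers of other cell types moved in the same libraries, among them the parietal epithelial marker Cd24a, which rose from 184 ± 14.6 to 1062 ± 75.9 CPM.

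**Figure D1:**
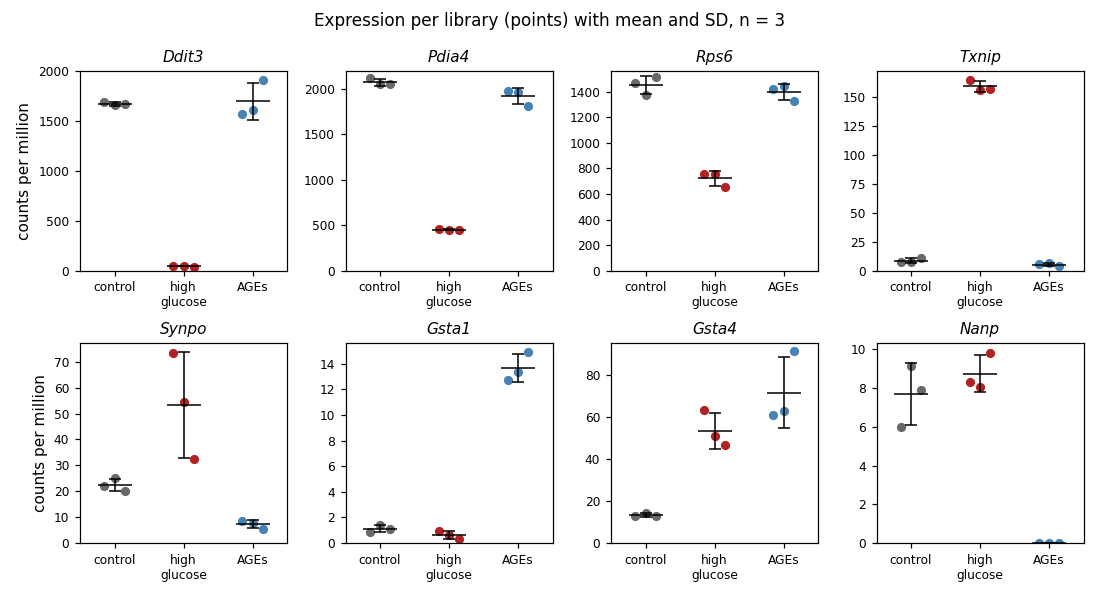
Expression of 8 genes in CPM (vertical axes, linear from 0) in each library, with points for libraries and bars for the mean and SD of the 3 libraries of a group. Ddit3 lies near 1672 CPM in control, near 47.3 in high glucose and near 1698 in AGEs, while Nanp has 0 counts in the 3 AGEs libraries.

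Ribosomal protein genes were also lower in high glucose. All 37 members tested fell, with a median log2 fold change of −0.84, and all 37 passed when adjusted over the list alone. Rps6 went from 1452 ± 68.2 to 724 ± 57.3 CPM (2.01-fold lower, adjusted p = 1.35e-05), Rpl4 from 2364 ± 59.8 to 1304 ± 34.7 CPM (adjusted p = 5.09e-06) and Rpl5 from 1688 ± 60.8 to 882 ± 34.0 CPM (adjusted p = 1.53e-05). The list took 4.53 ± 0.36% of counts in control and 2.78 ± 0.13% in high glucose. It was lower by camera (adjusted p = 8.47e-17), and the call was lost with an estimated correlation (adjusted p = 0.38 with an estimated correlation). Ribosomal protein genes have many near-identical pseudogenes, so the counts of single members are uncertain.

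Among the largest rises, Adgra1, an adhesion G protein-coupled receptor, was at 0.234 ± 0.0951 CPM in control and 34.1 ± 2.56 CPM in high glucose (log2 fold change 7.18, SE 0.89, adjusted p = 0.000215). Bmf, a BH3-only promoter of apoptosis, rose by 6.18, the cytokine gene Csf3 by 5.91, and the transcriptional coactivator Eya2 by 5.57 on the log2 scale. Cldn9 and Ly6f rose by 6.58 and 5.65 from 4 and 6 counts over the 3 control libraries. Over the alternatives these values ranged from 1.29 to 10.25 for Cldn9 and from 1.47 to 9.82 for Ly6f. Gper1, a receptor for oestrogen, rose by 5.12, but it overlaps 3110082I17Rik on the opposite strand, which had 24844 counts against 854. That neighbour had 2383 to 2493 counts in control and 2160 to 3270 in high glucose. Padi1, a peptidylarginine deiminase, rose by 4.71 (adjusted p = 0.0195), and that call was lost with DESeq2 (adjusted p = 0.0631) and without high glucose library 1 (adjusted p = 0.0538). Its control counts were 0, 34 and 0, and over the alternatives the log2 fold change of Padi1 ranged from 1.05 (limma on log2(FPKM + 1)) to 11.24 (without control library 2) and its adjusted p from 5.28e-05 to 0.0631. Among the largest falls, Ubap1l was at least 213-fold lower and Ostn, which encodes a secreted peptide, at least 174-fold lower, both with 0 counts in high glucose. Acox2, a peroxisomal oxidase, was 26.1-fold lower (117 ± 8.99 to 4.46 ± 0.184 CPM, adjusted p = 9.79e-07). Soat2, which esterifies cholesterol, fell by 5.09 on the log2 scale. Avil, an actin-binding protein, fell by 6.38, but it overlaps Tsfm on the opposite strand. Tsfm had 3990 to 4200 counts in control and 3257 to 5161 in high glucose. Car6 and Cox6a2 fell to 4 counts each over the 3 high glucose libraries.

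In carbon metabolism, the glucose transporter gene Slc2a1 was 2.39-fold lower in high glucose (482 ± 22.6 to 202 ± 11.4 CPM, adjusted p = 1.89e-05). Of 21 members of the glycolysis and glucose transport list, 4 rose and 6 fell, Eno2 and Pgk1 by −1.58 and −0.61, and the list was not called by camera (adjusted p = 0.361). Of 18 members of the fatty acid oxidation list, 9 rose and 1 fell. Pdk4, which restrains pyruvate entry into the mitochondrial cycle, rose 4.87-fold (5.28 ± 0.637 to 25.7 ± 1.55 CPM, adjusted p = 4.17e-06), and Cpt1a, which carries fatty acids to mitochondria, rose from 63.6 ± 1.29 to 127 ± 9.70 CPM. That list was higher by camera (adjusted p = 0.0372, and adjusted p = 0.324 with an estimated correlation). Of 19 members of fatty acid synthesis and storage, 8 rose, among them the desaturase Scd2 by 1.08 and the elongase Elovl6 by 1.38, and 3 fell (camera adjusted p = 0.126). In cholesterol biosynthesis 7 of 25 rose and 8 fell, with Fdps at −0.87, Lss at −0.68 and Pmvk at 0.66 (camera adjusted p = 0.812). The osmotic stress list had 6 of 12 members higher and 2 lower, with the taurine transporter Slc6a6 at 1.05 and the water channel Aqp1 at 2.07 (camera adjusted p = 0.164). Adjusted over the list alone, 10 members of fatty acid synthesis rose and 3 fell, 8 of cholesterol biosynthesis rose and 8 fell, and the counts of the other lists of this paragraph were the same. The tubular marker Cdh16 rose in the same libraries from 98.8 ± 2.46 to 314 ± 13.0 CPM.

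In the extracellular matrix and TGF-beta list 19 of 33 members rose and 3 fell, with a median of 0.92. The lysyl oxidase Loxl2 rose 2.96-fold (132 ± 6.33 to 392 ± 27.0 CPM, adjusted p = 1.41e-05), the matricellular gene Sparc 1.89-fold and the collagen chain Col6a1 5.34-fold. This list was higher by camera (adjusted p = 0.000592, and adjusted p = 0.38 with an estimated correlation). Among NF-kB and inflammatory mediators 16 of 32 rose and 4 fell, with Nfkbia, the inhibitor of NF-kB, at 1.27, Tlr2 at 0.90 and the cyclooxygenase Ptgs2 at −1.31 (camera adjusted p = 0.00831, and adjusted p = 0.46 with an estimated correlation). Of 43 interferon-stimulated genes 16 rose and 6 fell, with Oasl1 at 2.47, Parp14 at 1.28 and the immunoproteasome subunit Psmb8 at 1.01. Their camera adjusted p was 0.0363 (adjusted p = 0.46 with an estimated correlation), and it was 0.053 without high glucose library 1. Of 20 immediate-early genes 4 rose and 8 fell, with Myc at −1.70, Dusp1 at −1.03 and Jun at −0.89 (camera adjusted p = 0.406). Dusp1 overlaps Ergic1 on the opposite strand, which had 103199 counts over all libraries against 55061. Adjusted over the list alone, 21 matrix genes rose and 3 fell, 5 immediate-early genes rose and 8 fell, and the counts of the other lists here were the same.

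Markers of other cell types were measured beside these groups. Some listed markers of each type except the parietal one did not pass the filter on low counts, so the numbers are of markers tested. Of 8 parietal epithelial markers 4 rose and 1 fell (5 and 1 adjusted over the list alone). Pax2 went from 4.58 ± 1.19 to 39.9 ± 4.90 CPM, and the list had a camera adjusted p of 0.0608, which was 0.0478 without high glucose library 3. Of 5 tubular markers 3 rose and 0 fell (camera adjusted p = 0.0447, and adjusted p = 0.387 with an estimated correlation), a call that was lost without control library 3 (adjusted p = 0.0691) or high glucose library 1 (adjusted p = 0.053). The call of Cubn among the 3 (adjusted p = 0.0279) was lost without 5 of the 6 libraries in turn (adjusted p = 0.0532 to 0.0924), with the replicate block (0.0581), no filter on low counts (0.0574) and the GC content and length offset (0.0501). Of 4 endothelial markers 2 rose, Egfl7 by 1.24 and Flt1 by 1.23, and the Flt1 call was lost without high glucose library 3 (adjusted p = 0.0586). The pericyte marker Mcam rose by 1.04 as the 1 of 6 mesangial and fibroblast markers. Of 8 leukocyte markers 2 rose, Cd14 3.73-fold and Csf1r 1.65-fold, and Cd68 fell by 1.20 on the log2 scale. The camera adjusted p was 0.283, 0.393 and 0.164 for the endothelial, mesangial and leukocyte lists. Of 11 nuclear and non-polyadenylated transcripts 3 rose and 0 fell, all of them histone genes, with H1f2 from 5.39 ± 1.19 to 54.1 ± 5.91 CPM (camera adjusted p = 0.248). Counts adjusted over the list alone were the same for these lists except the parietal one. Fry, which tests whether the members of a list move 1 way without regard to other genes, called 23 of the 28 lists in high glucose against control. The 5 others, glycolysis, cholesterol biosynthesis, oxidative phosphorylation, AGE receptors and immediate-early genes, had an adjusted p of 0.0851 or more.

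In the cell cycle list 20 of 36 members rose and 10 fell (22 and 12 adjusted over the list alone), with a camera adjusted p of 0.0273 (adjusted p = 0.416 with an estimated correlation). Bub1b, a mitotic checkpoint kinase, rose 3.54-fold (49.2 ± 3.58 to 174 ± 9.73 CPM, adjusted p = 6.86e-06), and the mitotic kinase Cdk1 rose 1.77-fold, while the replication licensing gene Cdc6 was 1.78-fold lower. Among p53 targets and apoptosis genes 5 of 26 rose and 17 fell. The polo-like kinase Plk2 was 3.74-fold lower (368 ± 9.93 to 98.6 ± 8.68 CPM, adjusted p = 4.66e-07), the exonuclease Aen fell by 1.16 and Sesn1 rose by 1.28 on the log2 scale. That list was lower by camera (adjusted p = 0.0056, and adjusted p = 0.324 with an estimated correlation). In autophagy and lysosome 5 of 33 rose and 17 fell (5 and 18 adjusted over the list alone), with the lysosomal channel Mcoln1 at −1.21 and the autophagy receptor Sqstm1 at −1.18 (camera adjusted p = 0.0163, and adjusted p = 0.46 with an estimated correlation). Among NRF2 targets and antioxidant enzymes 13 of 30 rose and 4 fell (14 and 5 adjusted over the list alone), with Gsta4 rising to 53.5 ± 8.68 CPM, Gsr 2.48-fold higher and Hmox1 2.64-fold lower. The camera adjusted p of that list was 0.0672, and it was 0.0449 with a mean CPM of at least 1 and 0.018 without high glucose library 3. In the heat shock list 4 of 13 rose and 3 fell (4 and 4 adjusted over the list alone), with the mitochondrial chaperonins Hspd1 and Hspe1 at −1.46 and −0.80 (camera adjusted p = 0.715).

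The mitochondrially encoded genes had 7 of 13 members higher and 0 lower, with mt-Nd1 at 0.81 and mt-Cytb at 0.80 on the log2 scale. The camera adjusted p was 0.0486 (adjusted p = 0.554 with an estimated correlation). That call was lost without control library 2 or 3 (adjusted p = 0.0967 and 0.0698) and without high glucose library 1 or 2 (adjusted p = 0.109 and 0.0687). Of 39 nuclear-encoded genes of oxidative phosphorylation 4 rose and 6 fell, with Cox7b at 0.59 and Ndufb3 at 0.58 (camera adjusted p = 0.809). Adjusted over the list alone, 4 of those rose and 1 fell, and the mitochondrially encoded counts were the same. The list median of −0.05 and mean of 0.0034 had different signs for oxidative phosphorylation, as did the median of 0.07 and mean of −0.06 for heat shock proteins, whose camera direction was down.

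Among the 24 podocyte markers that passed the filter on low counts, out of a longer list, 10 rose and 3 fell (camera adjusted p = 0.156). The motor protein Myo1e rose 2.30-fold (to 57.6 ± 3.64 CPM, adjusted p = 9.36e-06), the intermediate filament Nes rose 2.69-fold and Vegfa was 2.13-fold lower. Synpo, an actin-associated podocyte protein, was at 22.4 ± 2.45 CPM in control and 53.4 ± 20.4 CPM in high glucose (log2 fold change 1.25, SE 0.27, adjusted p = 0.00543). Podxl, which encodes podocalyxin, had a log2 fold change of 0.10 (adjusted p = 0.6, and −0.03 to 0.27 over the alternatives). Nphs1, which encodes nephrin, had counts from 280 to 7040 across the 9 libraries and a log2 fold change of −0.65 (SE 1.14, adjusted p = 0.699), which ran from −2.50 to 0.64 over the alternatives, and it overlaps Rps12-ps4 on the opposite strand. The list of AGE receptors and glyoxal detoxification had 5 of 17 members higher and 3 lower (camera adjusted p = 0.406). Ager, the receptor RAGE, rose from 0.605 ± 0.403 to 2.54 ± 1.20 CPM (adjusted p = 0.0106), S100a4 rose by 2.21 and Lgals3, which encodes galectin-3, fell by 1.46 on the log2 scale. In the actin and focal adhesion list 10 of 32 rose and 3 fell, with Tpm1 at 0.88 and Pxn at 0.96 (camera adjusted p = 0.175). Among Notch, Wnt and Hippo targets 8 of 19 rose and 5 fell, with Notch1 at 1.05, Tcf7 at 1.16 and Ankrd1 at −1.63 (camera adjusted p = 0.33). Counts adjusted over the list alone were the same for these 4 lists. The parietal marker Epcam rose by 0.80 on the log2 scale in the same libraries.

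**Figure D2:**
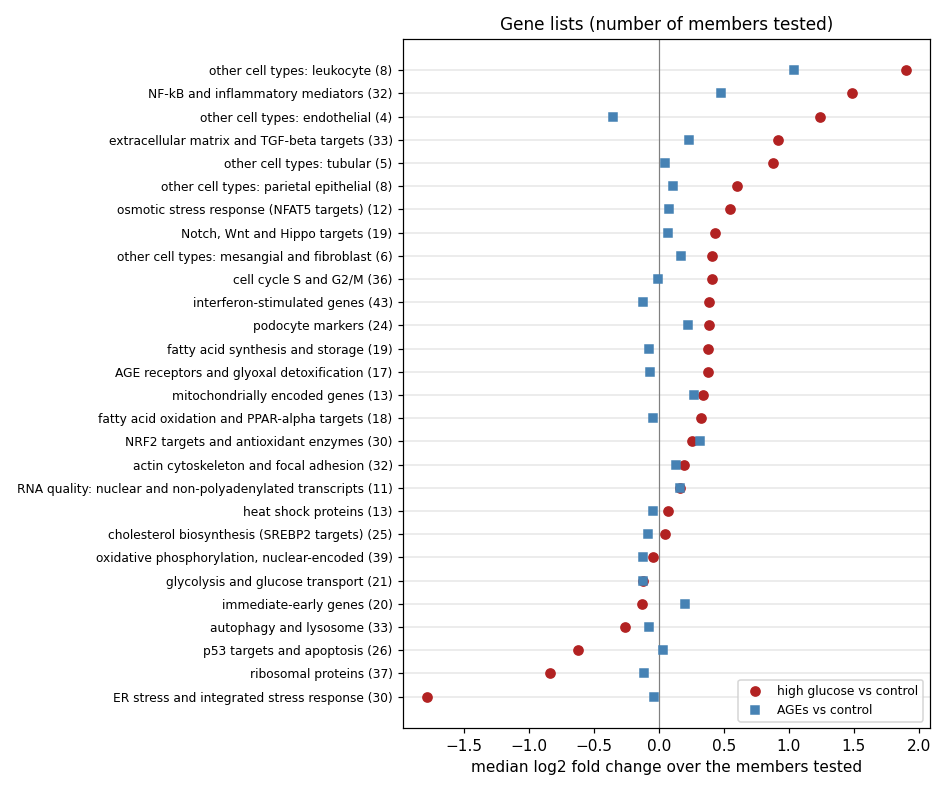
Median log2 fold change (horizontal axis) over the tested members of each of the 28 gene lists, for high glucose (circles) and AGEs (squares) against control, with the number of members tested beside each name. The ER stress list lies at −1.78 in high glucose and −0.04 in AGEs, and the ribosomal protein list at −0.84 and −0.11.

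To evaluate the response to AGEs, the AGEs libraries were compared with control. The 3 largest rises among the called genes were in glutathione transferases. Gsta1 rose 12.0-fold from 1.13 ± 0.243 to 13.7 ± 1.11 CPM (log2 fold change 3.59, SE 0.37, adjusted p = 0.0104), Gsta3 rose 9.04-fold from 1.35 ± 0.144 to 12.2 ± 2.94 CPM (adjusted p = 0.00408), and Gsta4 rose 5.37-fold from 13.4 ± 0.789 to 71.6 ± 17.1 CPM (adjusted p = 0.0015). Nqo1, a quinone reductase under NRF2 control, rose 2.12-fold (adjusted p = 0.0148). Of the metal-binding metallothioneins, Mt1 was lower by 1.70-fold (551 ± 6.19 to 324 ± 21.2 CPM, adjusted p = 0.0104) and Mt2 by 1.85-fold (adjusted p = 0.0374). In all, 15 of 17680 genes were called by the edgeR quasi-likelihood test, 9 higher and 6 lower, and 2190 had an unadjusted p under 0.05. DESeq2 called 325, which included the 15. A change of at least 2-fold was seen in 9 of the 15, 6 higher and 3 lower. Without AGEs library 1, 14 genes were higher and 7 lower, without AGEs library 3, 9 and 12, and the count was 5 with the replicate number as a block.

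The other genes that rose in AGEs were Fgfr1op, a centrosomal protein (2.49-fold, adjusted p = 0.0104), the basement membrane gene Nid1 (2.24-fold, adjusted p = 0.0161), Suclg2, a subunit of succinyl-CoA ligase (1.87-fold, adjusted p = 0.0128), Eps8, an actin regulator (1.71-fold, adjusted p = 0.0436), and Pgd of the pentose phosphate pathway (log2 fold change 0.64, adjusted p = 0.0395), which was named after its values were seen. The other genes that fell were Nanp, which dephosphorylates sialic acid phosphate, Zfp784 (3.86 ± 0.0267 to 0.0646 ± 0.0569 CPM, adjusted p = 0.0161), the long non-coding RNA Dleu2 (6.06-fold lower, adjusted p = 0.0015) and Cd2bp2, a splicing factor (1.73-fold lower, adjusted p = 0.00906). Nanp had 7.69 ± 1.58 CPM in control and 0 counts in all 3 AGEs libraries, so it was at least 520.9-fold lower (adjusted p = 0.000222). Nanp (ENSMUSG00000053916) lies on chromosome 2 from 151029685 to 151039398, minus strand, and Gsta1 (ENSMUSG00000074183) on chromosome 9 from 78230656 to 78242684, plus strand. Gsta1 has a near-identical neighbour, Gsta2, with a log2 fold change of 3.79 (adjusted p = 0.317), so reads may be split between them. Zfp784 overlaps Zfp865 on the opposite strand, which had 12399 counts over all libraries against 790. Mt2 overlaps Gm45774 on the opposite strand, which had 25209 counts against 293510. Calls were lost without control library 1 for Fgfr1op (adjusted p = 0.0595), Suclg2 (0.0595), Mt1 (0.0582), Gsta1 (0.0582) and Nqo1 (0.0582), and without control library 3 for Gsta1 (0.0514) and Nqo1 (0.0758) or control library 2 for Nqo1 (0.063). Zfp784 lost its call without control library 1, 2 or 3 (0.0609, 0.063 and 0.0678) or AGEs library 2 (0.0585), and Nid1 without control library 1 or 2 (0.0827 and 0.0847) or AGEs library 1 or 2 (0.055 and 0.0526). Mt2 and Eps8 lost theirs without any 1 of the 6 libraries, with adjusted p from 0.061 to 0.127 for Mt2 and from 0.086 to 0.165 for Eps8. With the replicate number as a block the 5 genes called were Gsta3, Gsta4, Fgfr1op, Nanp and Dleu2, and the adjusted p was 0.0741 for Gsta1, Nid1, Nqo1, Suclg2, Zfp784, Cd2bp2 and Mt1, 0.152 for Mt2 and 0.229 for Eps8. With limma on log2(FPKM + 1) and log2(FPKM + 0.1) the calls of Nid1 (0.0731 and 0.0683) and Eps8 (0.106 and 0.114) were lost, and that of Eps8 also with no filter on low counts (0.0536) and in a fit of the 6 libraries (0.0897).

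Among NRF2 targets and antioxidant enzymes 4 of 30 rose and 0 fell, and 17 rose when adjusted over the list alone. The list was higher by camera (median 0.32, adjusted p = 1.55e-11, and adjusted p = 0.339 with an estimated correlation). Among NF-kB and inflammatory mediators 0 of 32 were called over all genes and 13 rose when adjusted over the list alone, with a median of 0.48 (camera adjusted p = 5.23e-07, and adjusted p = 0.418 with an estimated correlation). Csf3 and Cxcl1, chosen after their values were seen, had log2 fold changes of 4.85 and 3.25 (adjusted p = 0.0623 and 0.117). No member of the other 26 lists was called by edgeR over all genes. Adjusted over the list alone, 2 podocyte markers rose and 1 fell, 2 actin genes, 1 p53 target and 1 parietal marker rose, and 1 gene each of fatty acid synthesis and of fatty acid oxidation fell. Camera placed 4 of these lists higher, with adjusted p of 0.00649 for podocyte markers, 0.0246 for matrix genes, 0.000901 for mitochondrially encoded genes and 0.0014 for actin genes (with an estimated correlation, adjusted p = 0.418, 0.576, 0.531 and 0.498). It placed 3 lower, with adjusted p of 0.00355 for oxidative phosphorylation, 0.0055 for ribosomal proteins and 0.0152 for cholesterol biosynthesis (with an estimated correlation, adjusted p = 0.636, 0.636 and 0.339). Without AGEs library 3, which stood apart on the second component, the adjusted p was 0.0894 for podocyte markers, 0.145 for matrix genes and 0.0894 for ribosomal proteins. The matrix call was also lost without control library 1 or 2 (adjusted p = 0.151 and 0.0659), the ribosomal protein and oxidative phosphorylation calls without control library 3 (adjusted p = 0.346 and 0.0844), and the cholesterol call without AGEs library 2 (adjusted p = 0.0609). Calls were gained without AGEs library 2 by AGE receptors (adjusted p = 0.0313), interferon-stimulated genes (0.0319) and glycolysis (0.0319), and without AGEs library 3 by leukocyte markers (0.0314). By fry, NRF2 targets were higher and cholesterol biosynthesis and endothelial markers lower (adjusted p = 0.00661 for each), and the adjusted p of the other 25 lists was 0.0845 or more. The ER stress list had a median of −0.04 with 0 members called (camera adjusted p = 0.326). The median, mean and camera direction differed in sign for fatty acid synthesis, the cell cycle, AGE receptors, heat shock proteins and mesangial markers.

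Among the podocyte genes, Synpo was at 7.24 ± 1.60 CPM in AGEs against 22.4 ± 2.45 CPM in control and did not pass (log2 fold change −1.63, SE 0.28, adjusted p = 0.117). It passed with DESeq2 (adjusted p = 8.3e-07) and in a fit of the 6 libraries of both groups (adjusted p = 0.0432), in a range up to 0.284 over the alternatives. Podxl had a log2 fold change of 0.56 (adjusted p = 0.233, and 0.0188 with DESeq2). Nphs1 had one of 1.45 (SE 1.15, adjusted p = 0.646) and Ager one of 0.48 (adjusted p = 0.744). Txnip and Arrdc4 were at −0.68 and −0.47 (adjusted p = 0.283 and 0.402), and Txnip passed with DESeq2 (adjusted p = 0.0421).

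**Figure D3:**
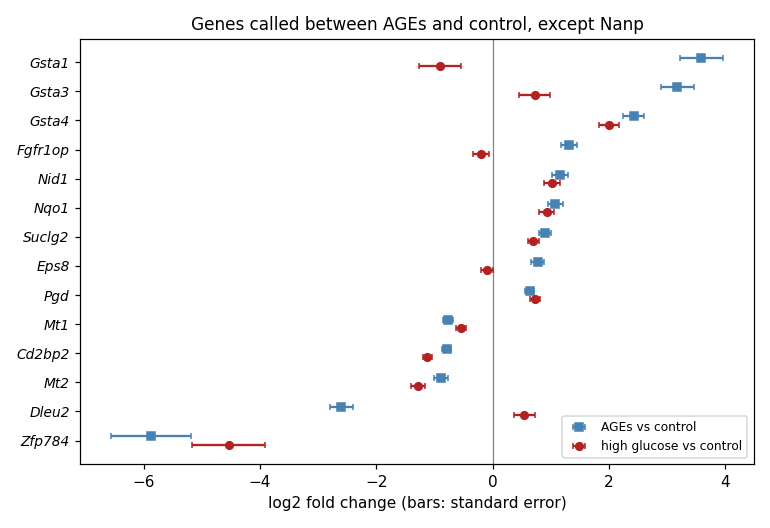
Log2 fold change with its standard error (horizontal axis) of the genes called between AGEs and control, except Nanp, in AGEs (squares) and in high glucose (circles) against control. Gsta1 lies at 3.59 in AGEs and −0.90 in high glucose, and Dleu2 at −2.60 and 0.55.

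To ask where the treatments differed, AGEs were compared directly with high glucose. The stress response genes that fell in high glucose were higher in AGEs, near their control level. Ddit3 was at 1698 ± 185 CPM in AGEs against 47.3 ± 3.96 CPM in high glucose (35.9-fold higher, adjusted p = 2.83e-08), and 29 of 30 members of the ER stress list were higher, with 0 lower and a median of 1.72. Txnip was 29.4-fold lower in AGEs (5.41 ± 1.23 against 159 ± 4.71 CPM, adjusted p = 9.42e-07). Synpo was 7.37-fold lower in AGEs (7.24 ± 1.60 against 53.4 ± 20.4 CPM, adjusted p = 6.33e-05). By the edgeR quasi-likelihood test 7053 of 17680 genes were called, 3481 higher and 3572 lower in AGEs, with 936 and 1524 of them at 2-fold or more. With limma on log2(FPKM + 1) the split was 2277 higher and 4813 lower (32.1% higher, against 49.4% by edgeR), and with a pseudocount of 0.1 it was 2274 and 4751 (32.4% higher). The median log2 fold change of all genes was −0.13 and −0.17 on these scales and −0.02 by edgeR.

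The ER stress list was higher in AGEs by camera (adjusted p = 1.51e-20), and this held with an estimated correlation (adjusted p = 0.000958). Of 37 ribosomal protein genes 36 were higher in AGEs and 0 lower, and 37 adjusted over the list alone, with Rpl4 1.85-fold and Rpl5 1.96-fold higher (camera adjusted p = 6.84e-15, and adjusted p = 0.392 with an estimated correlation). Interferon-stimulated genes had 2 of 43 higher and 18 lower (3 and 19 adjusted over the list alone), with Oasl1 4.50-fold lower (camera adjusted p = 0.00444, and adjusted p = 0.392 with an estimated correlation). Matrix genes had 3 of 33 higher and 14 lower (3 and 16 adjusted over the list alone), with Col6a1 at −2.32 on the log2 scale (camera adjusted p = 0.0055, and adjusted p = 0.392 with an estimated correlation). Of p53 targets 15 of 26 were higher and 5 lower (18 and 5 adjusted over the list alone), with Plk2 4.98-fold higher (camera adjusted p = 0.0055, and adjusted p = 0.309 with an estimated correlation). In fatty acid oxidation 1 of 18 was higher and 11 lower (2 and 11 adjusted over the list alone), with Pdk4 6.62-fold lower (camera adjusted p = 0.00675, and adjusted p = 0.192 with an estimated correlation). In the cell cycle list 8 of 36 were higher and 21 lower, the same counts as adjusted over the list alone, with Bub1b 3.05-fold lower (camera adjusted p = 0.0142, and adjusted p = 0.392 with an estimated correlation). Hmox1, the heme-degrading oxygenase, was 3.45-fold higher in AGEs, and Slc7a11, the cystine transporter, 3.19-fold higher, although the NRF2 list was not called (camera adjusted p = 0.438). Gsta1 was 22.4-fold higher (adjusted p = 2.76e-05). Nanp was at least 591.5-fold lower (adjusted p = 1.97e-06). Of the genes named in this paragraph, only Gsta1 and Nanp were also called between AGEs and control. Hmox1 was at 357 CPM in control, 135.5 in high glucose and 467 in AGEs, and Slc7a11 at 25.1, 15.9 and 50.6 CPM. Of markers of other cell types, 4 of 8 parietal markers were lower in AGEs and 1 higher, 3 of 5 tubular, 2 of 4 endothelial and 1 of 6 mesangial markers were lower, and 2 of 8 leukocyte markers were lower and 1 higher. Cd24a was 5.48-fold, Pax2 7.88-fold and Cdh16 3.07-fold lower, and the camera adjusted p of these 5 lists was 0.106 to 0.402. The 1 leukocyte marker that was higher, Cd68 (adjusted p = 0.0336), overlapped between the groups and lost its call without 4 of the 6 libraries in turn (0.0961 to 0.124), with limma on FPKM (0.137 and 0.142) and in a fit of the 6 libraries (0.0668). Of 11 nuclear and non-polyadenylated transcripts 0 were higher in AGEs and 3 lower, the histone genes H1f2 (7.60-fold), H2bc4 (6.56-fold) and H4c9 (2.95-fold), with a camera adjusted p of 0.547. Without AGEs library 3, calls were gained by tubular markers and autophagy (0.0461 for each) and fatty acid synthesis (0.047). Fry called 19 of the 28 lists between AGEs and high glucose, and the adjusted p of the other 9 was 0.076 or more. Podxl was 1.37-fold higher (adjusted p = 0.0218), a call that was lost without AGEs library 3 (adjusted p = 0.0624) or high glucose library 1 (adjusted p = 0.079) and with limma on FPKM (adjusted p = 0.14 and 0.142).

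The fold changes of the treatments against control were then set side by side. Of the 9 genes higher in AGEs 5 were also higher in high glucose (Gsta4, Nid1, Suclg2, Nqo1 and Pgd), against 1.76 from independent lists of 3466 and 9 genes. Of the 6 lower in AGEs 4 were also lower in high glucose (Mt1, Mt2, Cd2bp2 and Zfp784), against 1.18 from independent lists. Dleu2 fell in AGEs and rose in high glucose by 0.55 (adjusted p = 0.0403). Across 17680 genes, which are not independent replicates, the Pearson correlation was 0.363, where 20 simulations of unchanged groups with the same controls gave 0.503 (0.464 to 0.535), and the Spearman correlation was 0.196 against a simulated 0.445. Among genes with a mean CPM of at least 5 the Pearson correlation was 0.183. The covariance was 0.338 against a simulated 0.212, a difference of 0.126. The simulated groups had no treatment effect, while 6946 genes were called in high glucose. A correlation below the simulated one therefore decides nothing about how alike the treatments are. The 3 control libraries are too few to split. The share of the common calls and of the correlation that comes from the shared controls therefore cannot be told.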

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

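Of the tests below, those of library size, of osmolarity and of 1 scaling factor per library were chosen only after the result was seen, and the offset for GC content and length was added after the data were seen.

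Of the 15 genes called between AGEs and control, 8 also differed between AGEs and high glucose by the direct edgeR test of that difference, and 3 of those 8 were called in both treatments against control. The log2 difference of AGEs from high glucose was 4.49 for Gsta1, 2.45 for Gsta3, 1.51 for Fgfr1op, 0.86 for Eps8, 0.39 for Mt2, 0.33 for Cd2bp2 and −3.15 for Dleu2. Nanp was at least 591.5-fold lower in AGEs than in high glucose. Mt2 and Cd2bp2 fell in both treatments, by 1.28 and 1.12 in high glucose and by 0.89 and 0.79 in AGEs. Dleu2 overlaps Trim13 on the chromosome, which had 747 to 1067 counts in control and 960 to 1218 in AGEs, while Dleu2 went from 682 to 1049 counts to 130 to 199.

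The fall of the ER stress list in high glucose remained after an offset per library for GC content and transcript length, with a median of −1.81 (quartiles −2.39 to −1.18) and 29 members called lower, which argues against these trends as the whole cause. High glucose libraries 1 and 3 had larger totals than every control library and library 2 a smaller one, and against the control mean their list medians were −1.72, −1.82 and −1.80 on the log2 CPM scale, which argues against library size (thinning to the smallest total moved little, to −1.78, and decides nothing). The higher osmolarity of the medium was judged from the osmotic stress list, whose median log2 fold change was 0.54, between the bounds set for an osmotic effect and against one. An osmotic effect and an effect of glucose itself cannot be told apart here, because no osmotic control was analysed. Both would be effects of the high glucose treatment, and such an effect on these genes is a hypothesis, found and tested on the same libraries. By mean CPM, Ddit3 ranked 29 in control, 4930 in high glucose and 32 in AGEs. The glucose level of the control medium is not given. Whether the control level or the high glucose level of these genes is the usual one for this line therefore cannot be told.

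The fall of the ribosomal protein genes in high glucose was weighed in the same way. With the GC content and length offset the list median was −0.73 (quartiles −0.85 to −0.66), with 37 members called lower, which argues against these trends as the whole cause. Reads moved to pseudogenes would raise the pseudogene share, but 317 ribosomal protein pseudogenes went from 0.702 ± 0.042% of counts in control to 0.432 ± 0.018% in high glucose, a log2 ratio of −0.70. The list median lay −0.87 from the median of all genes tested (0.03). A wrong scaling factor moves all genes of a library alike and leaves this distance unchanged. Such a factor could therefore not make the list fall relative to other genes, whatever the data. The distance nearly restates the list median and decides nothing about the factor itself. Whether the transcripts fell in absolute amount cannot be told from these counts. A treatment effect on them is a hypothesis, found and tested on the same libraries, and the list's call was lost with an estimated correlation (camera adjusted p = 0.38).

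Nanp had 383 to 630 counts in control, 408 to 781 in high glucose and 0 in all 3 AGEs libraries. Counting that drops single genes at random was tested on genes with 3 or fewer counts in exactly 3 libraries and 100 or more in the other 6. There were 4 such genes, and in all 4 the low libraries were 1 group, against 0.143 expected by chance (one-sided exact binomial p = 1.63e-06). Other genes had 3 or fewer counts in a library and 100 or more in another of its group. They numbered 42 in control, 43 in high glucose and 83 in AGEs, and were not among the 4. The bound set beforehand against a counting error was met, but it was a poor bound, since 3 of the 4 genes (Myom2, Ostn and Dthd1) were low in high glucose, where 6946 genes were called, and Nanp alone was low in AGEs. A counting error and a treatment effect on Nanp therefore cannot be told apart from 1 gene.

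For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split called 6946 genes for high glucose against control, 15 for AGEs against control and 7053 for AGEs against high glucose, and the highest of the other splits called 2, 3 and 1. In each comparison 1 of the 10 splits, the real one, reached the real count. Every other split has libraries of both groups on each side. A difference between the groups then adds to the spread and lowers the counts of those splits, so they are no separate support.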

How the results depend on the processing

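The alternatives were planned except the offset for GC content and length, which was chosen after seeing the data. With a log2 fold change of at least 1 as well, which can only remove calls, 2419 genes were called between high glucose and control, 9 between AGEs and control and 2460 between AGEs and high glucose. The AGEs count against control was 325 with DESeq2 and 5 with the replicate block, and the cause was not tested. Leaving out each library in turn gave 5737 to 6133 genes for high glucose against control, 10 to 21 for AGEs against control (of which 5 to 12 were among the 15) and 5975 to 6876 for AGEs against high glucose, with fewer libraries in each fit. No pairing by replicate number was visible, with deviations of same-numbered libraries correlating from −0.067 to 0.084 over 9 pairs. The labels do not say whether such libraries were handled together. The block gave 6322 and 6390 genes in the other 2 comparisons. With the GC content and length offset the counts were 7482, 21 and 7456. The correlation between the treatments was 0.1956 by Spearman, 0.1828 among genes with a mean CPM of at least 5 and 0.5193 to 0.5392 without 1 control library, and the cause was not tested. In the AGEs comparison, Gsta3, Gsta4, Nanp and Dleu2 kept their calls under all 16 alternatives. Of the values of named genes under the alternatives, 1585 of 1625 in high glucose, 268 of 320 in AGEs and 1449 of 1498 between the treatments kept their side of the threshold, and 0 calls turned direction. Nphs1 and Podxl, not called in high glucose, ran from −2.4987 to 0.6373 and from −0.0335 to 0.267 on the log2 scale. Of 252 values of the lists in each comparison, 232, 231 and 243 did, and 0 calls turned direction. Many of these values belong to lists that were not called. The estimated correlation alone removed 10 camera calls in high glucose, 9 in AGEs and 6 between the treatments. Only the ER stress list kept a call with it, in high glucose and between the treatments. Limma on FPKM was run as an alternative, while the alternatives meant only for a table without counts were not run, since counts were available. Genes with 4 or fewer counts over a group give folds that depend on the fitted prior.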

Other observations

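The KEGG pathways below were chosen and tested only after the data were seen, and 0 of 288 kept a call with an estimated correlation in any comparison. Camera called 89 pathways higher and 8 lower in high glucose, 20 and 3 in AGEs, and 10 and 41 in AGEs against high glucose. Beside the ribosome (6 of 105 genes higher and 81 lower), ribosome biogenesis had 3 of 64 genes higher and 41 lower in high glucose, with a median of −0.50 (camera adjusted p = 1.54e-07, and 0.171 with an estimated correlation). In AGEs the same pathway had 0 genes called and a median of 0.16 (camera adjusted p = 5.4e-06, and 0.696 with an estimated correlation). Genes of the folate one-carbon pool, which feeds nucleotide synthesis, had 1 of 19 higher and 10 lower in high glucose (median −0.57, adjusted p = 0.00174). Aminoacyl-tRNA biosynthesis, which charges transfer RNAs for translation, had 6 of 39 higher and 20 lower (median −0.32, adjusted p = 0.00214). DNA replication had 1 of 29 higher and 14 lower (median −0.29, adjusted p = 0.00463), in the libraries where the mitotic genes Bub1b and Cdk1 rose.

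Axon guidance, a set of guidance receptors and ligands that epithelial cells also use, had 66 of 146 genes higher and 15 lower in high glucose (median 0.46, camera adjusted p = 0.00174). The systemic lupus erythematosus pathway, which is made up largely of histone genes, had 16 of 52 higher and 0 lower (median 1.16, adjusted p = 0.000925). The AGE-RAGE signalling pathway had 43 of 89 genes higher and 14 lower in high glucose (median 0.49, adjusted p = 0.00363, and 0.231 with an estimated correlation). In AGEs against control the pathways of glutathione metabolism and of drug metabolism by cytochrome P450 had 4 of 51 and 3 of 41 genes higher and 0 lower (adjusted p = 0.0138 and 0.013, and 0.713 with an estimated correlation for both).

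The most abundant gene in control was the ER chaperone Calr at 14590 CPM. It was 5th in high glucose, at 3137 CPM, and 1st in AGEs, at 12650 CPM. The ER chaperones Hsp90b1 and Hspa5 ranked 4 and 6 in control and 22 and 13 in high glucose. Ddit3 ranked 29 in control, 4930 in high glucose and 32 in AGEs. These genes were chosen after their values were seen.

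The number of genes with 3 or fewer counts in at least 1 library of a group and 100 or more in at least 1 other library of it was 42 in control, 43 in high glucose and 83 in AGEs.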
